A study of Homo sapiens with 6 samples.

How the data were processed

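RNA was sequenced from SW1353 human chondrosarcoma cells in 6 samples, 3 transduced with a firefly luciferase shRNA and 3 with an shRNA labelled SIRT1. Per the labels' protocols, cells were kept in 3% oxygen for 48 h after seeding, total RNA was extracted with TRI reagent, and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes the tools were Trimmomatic, STAR and DESeq2 and the genome build was GRCh38; their versions, the read counter, the annotation release and whether counting used the strand are not given in the sources used here. Per the design text the 3 samples of a group were biological replicates.

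One table for the whole series was used. Its read counts per gene are the authors' raw counts, per the file headers, and are whole numbers. A second block of columns holds normalized counts that the authors rounded to whole numbers, treated here as a score, and the authors' group means of these are a score too; neither entered a test. The authors' comparison of shSIRT1 with the control is given as a linear fold change (ratio), a log2 fold change, a p-value and an adjusted p-value, per the file headers. Columns named for control and hairpin replicates were matched to samples by name; neither column order nor values were used. The table lists 60691 genes, of which 32875 had at least 1 read; 45 are copies of pseudoautosomal genes on the Y chromosome. Gene symbols came from the table. Coordinates and biotypes came from GENCODE 29 on GRCh38, matched by Ensembl identifier without version (58504 genes, of which 40332 also had the same version), so gene boundaries may differ from those the authors used. Mitochondrially encoded genes were not analysed here, so the planned share of mitochondrial counts was not computed.

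Replicates were compared before averaging: a chi-square statistic per gene between libraries was 2.82 to 6.10 within groups and 57.4 to 89.7 between groups, so no pair agreed within sampling noise and each library counted as 1 replicate. Genes were kept by edgeR filterByExpr with default settings (16591 tested). Counts were scaled by TMM, with factors of 0.948 to 0.970 for shfirefly and 1.038 to 1.048 for shSIRT1, and tested by edgeR's quasi-likelihood F test (estimateDisp, robust glmQLFit, glmQLFTest) on group alone. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was said to rise or fall at an adjusted p under 0.05. CPM values use TMM-scaled library sizes. Standard errors of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.0541. Where either group held few counts, ratios of counts over the TMM-scaled library sizes, each summed over a group, are given with 95% exact conditional intervals, which cover counting error only. The upper limit that a count of 0 allows was set at 3 counts per library, over the same library sizes.

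The design, the tests, the alternatives and 44 gene lists were fixed before the data were examined. Of 1400 list entries 1385 matched a gene in the table, and 43 lists had at least 5 tested members; the list of mitochondrially encoded genes was not analysed here. Lists share members, so their tests are not independent. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 43 lists, and again with the correlation estimated per list and with fry. Camera compares a list with the other genes, while fry asks whether its genes move, on balance, one way. Named genes followed a rule fixed in the same way: SIRT1, EPAS1, HIF1A and ARNT; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and CPM ranges of the groups that did not overlap; and from each list up to 2 rising and 2 falling called members with the largest change. That rule gave 160 genes, not all of which are described. A further 21 genes were chosen after their values were seen. Of all 181, 49 overlap another annotated gene on the same strand and 94 on the other strand, and reads of such genes may be shared or, if counting ignored the strand, mixed.

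Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, quasi-likelihood fits without robust estimation, adjustment over each list alone, and leaving out each library in turn. Chosen after seeing the data were scaling by library totals alone, an offset for transcript GC content and length (natural splines with 5 degrees of freedom per library; 99.1% of tested genes had both values), and a fit without both libraries numbered 3. Shares of counts, total counts and genes with at least 10 counts per library were compared by exact two-sided permutation tests. The smallest possible p of these tests is 0.1. The share of histone genes was not among the planned measures.

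The procedure was tested on simulated counts for 16323 genes with the means and library sizes of this comparison, 200 of them changed. It recovered 34% of genes changed 1.2-fold, 78% at 1.5-fold, 76% at 2-fold and 98% at 4-fold, with 0 wrong signs; of 152 genes called, 9 (5.92%) were unchanged. Of 40 lists drawn at random, 0 were called by camera with the preset correlation and 0 with the estimated one. The simulated changes were few and as often up as down, whereas 8760 of 16591 genes were called in the real comparison. Rates of recovery and of false calls may therefore differ there. Simulated genes were drawn independently of each other. The simulation therefore could not show how the list tests behave when the genes of a list are correlated. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1 and pandas 2.3.3.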

Results

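Gene expression was measured by RNA sequencing in SW1353 cells, an established human chondrosarcoma line, which is a malignant cartilage-forming tumour of bone. The cells had been kept in 3% oxygen for 48 h after seeding and carried a lentiviral short hairpin RNA (shRNA). The 6 libraries fell into 2 groups of 3 biological replicates: shfirefly, a control hairpin against an insect luciferase that human cells lack, and shSIRT1, a hairpin labelled as directed against SIRT1, an NAD+-dependent deacetylase of histones and transcription factors. The total counts were 32044191, 28556696 and 31996688 in the shfirefly libraries and 29455792, 29564361 and 24993064 in the shSIRT1 libraries. At these depths a gene with no counts could still have been present at up to 0.0968 to 0.115 CPM (counts scaled to a library of a fixed size), a limit of 3 counts that covers counting error only. The comparison addressed how SIRT1 relates to transcription driven by HIF-2α, the hypoxia-inducible factor subunit encoded by EPAS1, and to the malignant behaviour of chondrosarcoma cells.

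SIRT1 mRNA was lower in every shSIRT1 library than in every shfirefly library. It stood at 12.9, 13.2 and 14.7 CPM in the shSIRT1 libraries and at 25.99, 24.8 and 24.0 CPM in the shfirefly libraries, which gave means of 13.6 ± 0.953 and 24.9 ± 0.984 CPM (SD, n = 3). That was a 1.83-fold lower level (log2 fold change -0.88 ± 0.07 SE, adjusted p = 2.3e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EPAS1 fell by a similar amount, from 456 ± 40.8 to 233 ± 10.5 CPM (SD, n = 3), a 1.96-fold lower level (log2 fold change -0.97 ± 0.06 SE, adjusted p = 5.8e-07). The labels differ on the hairpin: sample names, treatment labels and the design text name SIRT1. The treatment protocol names EPAS1 instead. The 2 genes fell together, so their levels fit either naming, and "shSIRT1" below stands for the libraries labelled so. ARNT, the shared partner of the HIF alpha subunits, fell from 49.3 ± 2.99 to 37.8 ± 1.62 CPM (SD, n = 3; log2 fold change -0.38 ± 0.06 SE, adjusted p = 5.8e-06). HIF1A, which encodes the other main alpha subunit, had 882 ± 11.2 CPM in shSIRT1 and 865 ± 51.5 CPM in shfirefly (SD, n = 3), with a log2 fold change of 0.03 ± 0.04 SE that did not pass the test (adjusted p = 0.59). HIF1A turned to -0.17 (adjusted p = 0.00042) once transcript GC content and length were corrected for and to 0.15 (adjusted p = 0.0083) when only library totals were used for scaling. SIRT1 lies on chromosome 10 (67884669 to 67918390, forward strand) and EPAS1 on chromosome 2 (46293667 to 46386703, forward strand) of GRCh38, both protein-coding and with no annotated gene overlapping either. HIF1A overlaps 1 annotated gene on the same strand and 2 on the other, and ARNT overlaps 1 on the same strand.

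**Figure D1:**
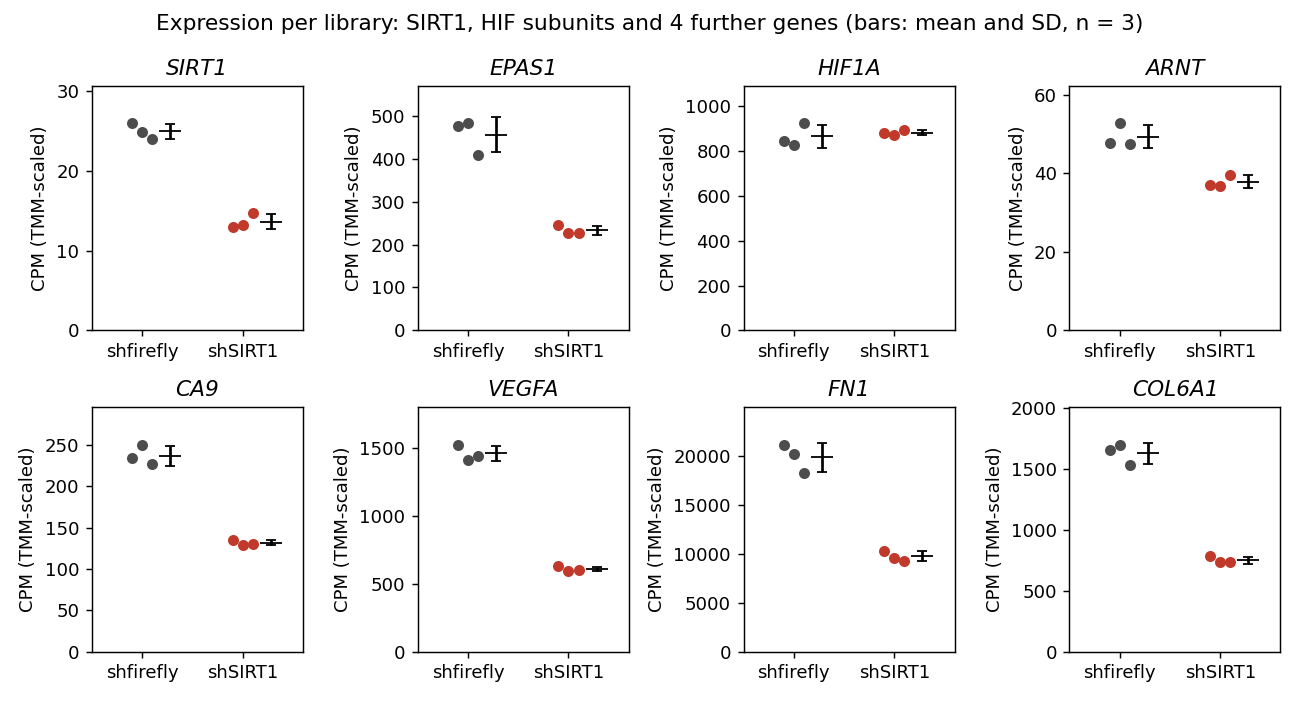
Expression in TMM-scaled CPM (vertical axes, each starting at 0) of SIRT1, EPAS1, HIF1A, ARNT, CA9, VEGFA, FN1 and COL6A1 in each of the 3 shfirefly (grey) and 3 shSIRT1 (red) libraries, with bars for the mean and SD. All shSIRT1 points lie below all shfirefly points for each gene but HIF1A, whose mean was 882 CPM in shSIRT1 and 865 CPM in shfirefly.

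Across the transcriptome the libraries separated by group, and a majority of the tested genes differed. Of 16591 genes tested, 8760 (52.8%) changed, with 4449 higher and 4311 lower in shSIRT1. Most of the changes were small: 363 genes rose and 707 fell by at least 2-fold. With scaling by library totals alone the split was 6225 higher and 3021 lower, because that scaling moved the median log2 fold change of all tested genes to 0.13. The CPM ranges of the groups did not overlap for 9911 genes (59.7%), where chance gives 10% for 3 against 3, and 8464 of these were among the genes called. The leading principal component held 66.1% of the variance and separated the groups, and the next held 10.7%. SIRT1 itself was far from the largest change, since 901 of the genes called fell by more. The abundant transcripts moved mostly downwards: of the 100 most abundant genes 72 fell, 12 rose and 16 did not pass the test. Their summed share of the counts was 21.7% ± 0.117 in shSIRT1 and 26.3% ± 0.425 in shfirefly (SD, n = 3; exact two-sided permutation test, p = 0.1, the smallest value that 3 against 3 allows).

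The largest fall among genes averaging at least 5 CPM was that of PXDN, which encodes peroxidasin, an enzyme that crosslinks collagen IV in basement membranes. It went from 10.4 ± 0.777 CPM in shfirefly to 0.423 ± 0.0328 CPM in shSIRT1 (SD, n = 3), a 24.3-fold lower level (log2 fold change -4.60 ± 0.17 SE, adjusted p = 1.2e-14). PXDN spans 1631887 to 1744852 on the reverse strand of chromosome 2. The other genes with the largest falls were the pseudogene AC138409.2 (12.1-fold lower), the calcium channel genes CACNA1H (6.82-fold lower) and CACNA1B (5.23-fold lower), the neuropeptide gene SPX (5.80-fold lower), lactoperoxidase LPO (5.15-fold lower), CHI3L1 (4.92-fold lower), the ryanodine receptor gene RYR1 (4.50-fold lower), LYPD5 (4.43-fold lower) and the kinase gene PNCK (4.19-fold lower). CHI3L1, a secreted glycoprotein made by chondrocytes in inflamed joints, fell from 51.8 ± 2.56 to 10.6 ± 1.06 CPM (SD, n = 3; adjusted p = 7.5e-16). Adjusted p-values of these 10 genes were 3.6e-05 or lower.

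ARHGAP36, which encodes an inhibitor of protein kinase A that activates hedgehog signalling, had the largest rise under the same rule. Its level was 13.03 ± 0.587 CPM in shSIRT1 and 2.05 ± 0.175 CPM in shfirefly (SD, n = 3), 6.35-fold higher (log2 fold change 2.67 ± 0.12 SE, adjusted p = 1.2e-13), and it spans 131058242 to 131089883 on the forward strand of chromosome X. Next came FAM111B (4.81-fold higher, adjusted p = 0.011), MROH2B (4.65-fold), the melanosome trafficking gene RAB38 (4.20-fold), the melanosome receptor gene GPR143 (3.48-fold), the actin-binding protein gene NEXN (3.34-fold), the neurofilament gene NEFL (3.23-fold), ZNF92 (3.23-fold), the homeobox gene RHOXF2 (3.18-fold) and the tight-junction gene CLDN4 (3.09-fold). FAM111B, NEXN and ZNF92 were highest in replicate 3 of each group. NEXN and ZNF92 varied between replicates, with 18.4 ± 8.01 and 11.9 ± 4.07 CPM in shSIRT1 (SD, n = 3). The call for both was lost without shfirefly replicate 1, without shfirefly replicate 2, without shSIRT1 replicate 1 and with no filter on low counts, and that for NEXN also without shfirefly replicate 3, with adjusted p up to 0.096 for NEXN and 0.099 for ZNF92. Genes below the 5 CPM floor included larger rises, and 3 of them were chosen after their values were seen. PLCXD3 rose from 0.865 ± 0.180 to 8.06 ± 1.27 CPM (SD, n = 3; 9.22-fold, adjusted p = 4.8e-12). IL20RA, an interleukin receptor subunit, had 267 counts in shSIRT1 and 3 in shfirefly, and IRS4, an insulin receptor substrate, had 192 and 7. The ratios of counts over scaled library sizes were 90.2 (95% exact interval 30.6 to 440.4) for IL20RA and 27.8 (13.2 to 70.1) for IRS4, intervals that cover counting error only. The log2 fold change of IL20RA was 6.32, and 7.14 without shfirefly replicate 1.

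**Figure D2:**
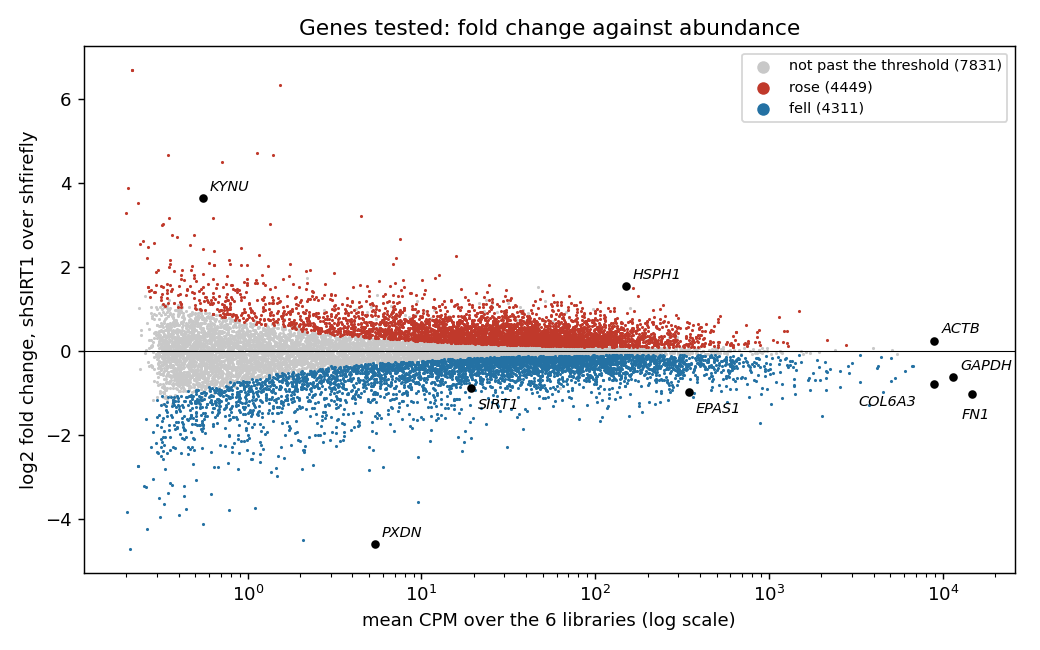
Log2 fold change of shSIRT1 over shfirefly (vertical axis) against mean CPM over the 6 libraries (horizontal axis, log scale) for the 16591 genes tested, with 4449 that rose in red, 4311 that fell in blue and the rest in grey. PXDN lies at -4.60, and the abundant FN1, GAPDH and COL6A3 lie below 0 while ACTB lies above it.

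Genes induced by low oxygen were lower in shSIRT1, and the fall covered every tested member of the main hypoxia list. All 35 tested members of the list of hypoxia-inducible genes outside glycolysis fell, 35 also when adjusted over the list alone, with a median log2 fold change of -0.80 (camera adjusted p = 3.2e-56; adjusted p = 0.15 with an estimated correlation). With the correction for GC content and length 34 of them fell, and with library totals alone 33. The lipid-droplet protein gene PLIN2 fell from 4.998 ± 0.394 to 1.42 ± 0.260 CPM (log2 fold change -1.82) and the collagen crosslinking enzyme gene LOX from 2991 ± 111 to 1021 ± 36.8 CPM (log2 fold change -1.55; SD, n = 3). A further 3 well-known members were chosen after their values were seen. VEGFA, the main angiogenic growth factor, fell from 1456 ± 57.8 to 609 ± 17.7 CPM. NDRG1 fell from 5345 ± 494 to 2205 ± 137 CPM and CA9, a membrane carbonic anhydrase, from 237 ± 12.2 to 132 ± 3.00 CPM (SD, n = 3; adjusted p of 7.6e-06 or lower for the 3 genes). Among 24 tested HIF-2α targets 17 fell, 3 rose and 4 did not pass, with the counts 17 and 3 also when adjusted over the list alone and a median of -0.69 (camera adjusted p = 1.2e-12; adjusted p = 0.15 with an estimated correlation). Of the 29 genes in this list 17 were also in another list, PLIN2 in the hypoxia list among them, so it gave no separate evidence. The members that rose included FLT1, a VEGF receptor (log2 fold change 1.10 ± 0.05 SE), and the G1 cyclin gene CCND1 (0.35 ± 0.04 SE). IL6, a further member, had 9 counts in shSIRT1 and 51 in shfirefly, a ratio of 0.179 (95% exact interval 0.0774 to 0.367). The log2 fold change of IL6 was -2.43, and -3.45 without shSIRT1 replicate 3. Glycolysis genes moved the same way: 21 of 24 fell, 1 rose and 2 did not pass, 21 and 1 also when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.4e-20; adjusted p = 0.16 with an estimated correlation). The glucose transporter gene SLC2A3 (log2 fold change -1.26 ± 0.06 SE) and the aldolase gene ALDOC (-1.22 ± 0.04 SE) fell the most, and the member that rose was PFKFB3 (0.19 ± 0.04 SE). PGK1 and GAPDH, abundant glycolytic enzymes chosen after their values were seen, had log2 fold changes of -0.71 and -0.63. Among 14 tested HIF pathway components 7 fell, 1 rose and 6 did not pass, 7 and 1 also when adjusted over the list alone (median -0.11, camera adjusted p = 0.028; adjusted p = 0.24 with an estimated correlation), and the list test was lost when library totals alone were used for scaling (adjusted p = 0.078, with 5 members higher and 5 lower). Its strongest falls were EPAS1 and the prolyl hydroxylase gene EGLN3 (log2 fold change -0.90 ± 0.05 SE), and HSP90AA1, a chaperone of HIF alpha subunits, rose (0.80 ± 0.04 SE). The list was not tested without EPAS1, a named hairpin target.

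Matrix and matrix-remodelling genes fell as groups. Of 37 tested collagen and other fibrillar matrix genes 28 fell, 3 rose and 6 did not pass, 28 and 3 also when adjusted over the list alone. Their median was -0.53 (camera adjusted p = 2.8e-27; adjusted p = 0.16 with an estimated correlation). LOX and the fibroblast protease gene FAP (log2 fold change -1.25 ± 0.30 SE) fell the most in this list, and fibrillin-2 (FBN2, 0.37 ± 0.05 SE) rose the most. The most abundant matrix transcript, fibronectin (FN1, chosen after its values were seen), fell 2.04-fold (adjusted p = 1.5e-09), and the collagen VI genes COL6A1 and COL6A3, chosen in the same way, fell 2.17-fold and 1.72-fold. Of 32 tested proteases and protease inhibitors 22 fell, 3 rose and 7 did not pass, 22 and 3 also when adjusted over the list alone. The list median was -0.47 (camera adjusted p = 1.8e-09; adjusted p = 0.15 with an estimated correlation). ADAMTS9 (log2 fold change -2.29 ± 0.27 SE) and stromelysin-2 (MMP10, -2.0 ± 0.19 SE) fell the most, while ADAMTS1 (1.01 ± 0.20 SE) and ADAMTS15 (0.74 ± 0.06 SE) rose. Interstitial collagenase (MMP1, chosen after its values were seen) fell from 4.72 ± 0.569 to 2.09 ± 0.266 CPM (SD, n = 3; adjusted p = 2.6e-06). Among 25 epithelial-mesenchymal and invasion genes 12 fell, 5 rose and 8 did not pass, with 12 lower and 6 higher when adjusted over the list alone. The median of these genes was -0.22 (camera adjusted p = 0.00042; adjusted p = 0.21 with an estimated correlation). With scaling by library totals alone, 11 of these fell and 9 rose, with a median of -0.10. Podoplanin (PDPN) fell by 2.12 on the log2 scale and the focal-adhesion gene TNS1 by 0.96, whereas the mesenchymal transcription factor gene PRRX1 rose (1.59 ± 0.35 SE).

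Secreted inflammatory factors were also lower. Of 16 tested senescence-associated secreted factors 11 fell, 1 rose and 4 did not pass, 11 and 1 also when adjusted over the list alone. As a list their median was -0.91 (camera adjusted p = 1.7e-08; adjusted p = 0.16 with an estimated correlation). IL6 and the IGF-binding protein gene IGFBP3 (1370.1 ± 81.3 to 414 ± 5.11 CPM, SD, n = 3) fell the most, and the growth factor gene FGF2 rose (log2 fold change 1.33 ± 0.10 SE). Of 25 NF-κB inflammatory targets 14 fell, 2 rose and 9 did not pass, 14 and 2 also when adjusted over the list alone. Members had a median of -0.40 (camera adjusted p = 0.0056; adjusted p = 0.23 with an estimated correlation). That median was -0.22 with the correction for GC content and length (13 lower, 3 higher) and -0.28 with library totals alone (13 lower, 4 higher). Complement C3 fell from 6.34 ± 0.109 to 1.81 ± 0.355 CPM, and CXCL8, the neutrophil chemokine interleukin-8 (chosen after its values were seen), from 6.84 ± 0.574 to 2.97 ± 0.288 CPM (SD, n = 3). TNFAIP2 (log2 fold change 0.43 ± 0.05 SE) and NFKB1 (0.30 ± 0.05 SE) rose.

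Proliferation genes moved in the opposite direction to the hypoxia genes. Of 46 S-phase and DNA replication genes 45 rose and 1 did not pass, and all 46 rose when adjusted over the list alone. Their median was 0.67 (camera adjusted p = 9.2e-27; adjusted p = 0.16 with an estimated correlation). The checkpoint adaptor gene CLSPN went from 27.0 ± 4.10 to 72.5 ± 4.11 CPM and the transcription factor gene E2F2 from 4.44 ± 0.141 to 11.02 ± 0.922 CPM, and MCM5, a subunit of the replicative helicase chosen after its values were seen, from 83.1 ± 2.02 to 162 ± 7.41 CPM (SD, n = 3). Of 49 G2 and mitosis genes 42 rose, 1 fell and 6 did not pass, with 44 higher and 1 lower when adjusted over the list alone. The list median was 0.47 (camera adjusted p = 1.2e-12; adjusted p = 0.24 with an estimated correlation). KIF18A, a mitotic kinesin, had the largest rise in this list (log2 fold change 1.38 ± 0.34 SE, adjusted p = 0.029), but its call was lost without shfirefly replicate 1, without shfirefly replicate 2, without shSIRT1 replicate 1 or with no filter on low counts (adjusted p up to 0.10). KIF18A was also highest in replicate 3 of each group. The cytokinesis gene ECT2 rose 2.23-fold (adjusted p = 0.0038). Of 38 homologous recombination and DNA repair genes 32 rose, 1 fell and 5 did not pass, with 33 higher and 1 lower when adjusted over the list alone. The median of these genes was 0.51 (camera adjusted p = 5.6e-12; adjusted p = 0.21 with an estimated correlation). The Fanconi anaemia gene FANCB (log2 fold change 1.52 ± 0.14 SE) and the recombination gene XRCC2 (1.22 ± 0.21 SE) led this list, and BRCA1, chosen after its values were seen, rose 1.92-fold. Among 35 MYC targets and ribosome biogenesis genes 31 rose, 3 fell and 1 did not pass, with 32 higher and 3 lower when adjusted over the list alone. As a list their median was 0.61 (camera adjusted p = 1.1e-13; adjusted p = 0.21 with an estimated correlation). The nucleolar assembly factor genes RRS1 (log2 fold change 1.36 ± 0.11 SE) and RRP9 (1.04 ± 0.10 SE) rose the most, while MYC itself fell from 85.3 ± 3.29 to 60.9 ± 3.29 CPM (SD, n = 3; adjusted p = 3e-08).

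**Figure D3:**
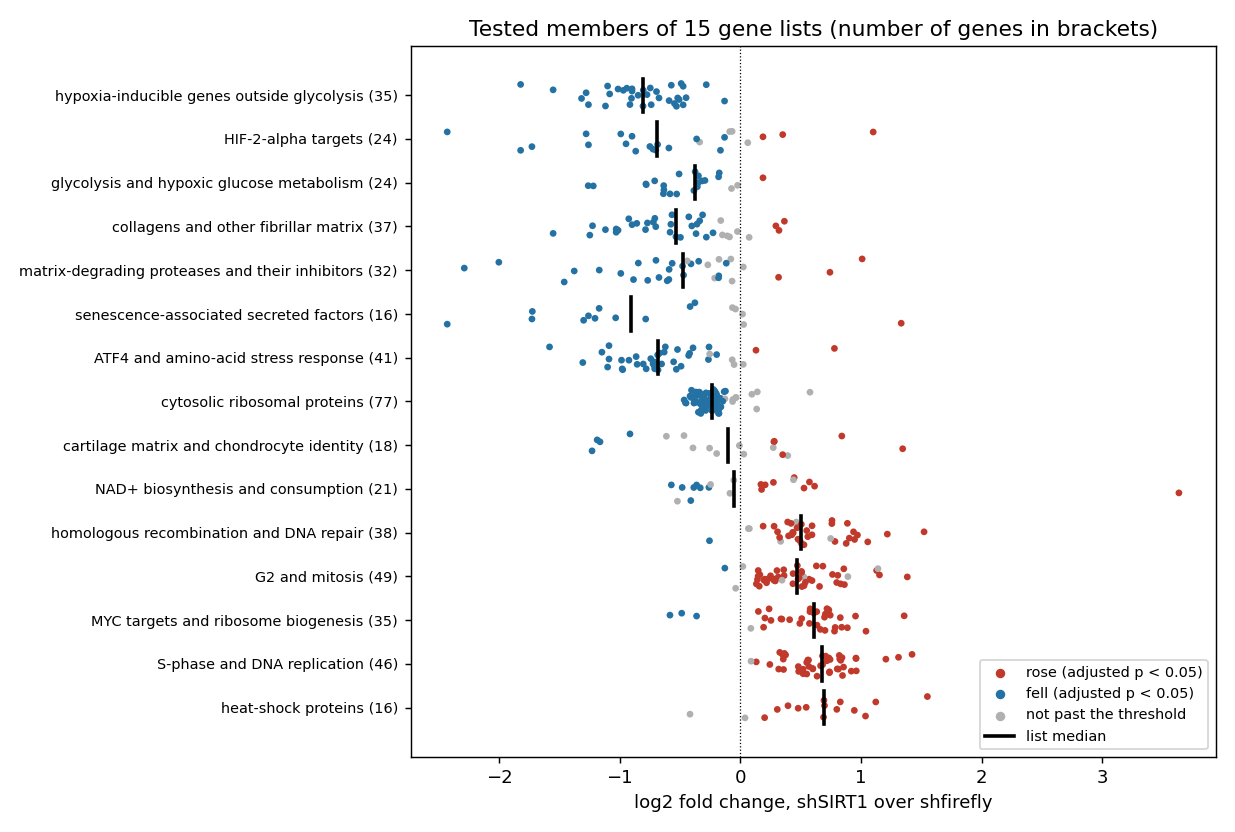
Log2 fold change of shSIRT1 over shfirefly (horizontal axis) for each tested member of 15 gene lists (the number of genes is in brackets), coloured red where it rose, blue where it fell and grey where it did not pass the threshold, with a black bar at the median. The medians run from -0.91 for senescence-associated secreted factors to 0.69 for heat-shock proteins, and all 35 hypoxia-inducible genes outside glycolysis lie below 0.

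Stress responses parted in direction. Of 41 ATF4 and amino-acid stress genes 35 fell, 2 rose and 4 did not pass, 35 and 2 also when adjusted over the list alone. Members had a median of -0.68 (camera adjusted p = 1.1e-30; adjusted p = 0.16 with an estimated correlation). DDIT3, the stress-induced factor CHOP, fell from 53.5 ± 4.14 to 17.9 ± 0.220 CPM and the pseudokinase gene TRIB3 from 168 ± 12.2 to 67.8 ± 3.11 CPM (SD, n = 3), while ATF5 rose 1.72-fold. Of 24 unfolded protein response genes 17 fell, 5 rose and 2 did not pass, 17 and 5 also when adjusted over the list alone. Their median was -0.25 (camera adjusted p = 9.4e-05; adjusted p = 0.21 with an estimated correlation). Scaling by library totals alone gave 13 lower and 6 higher, with a median of -0.13. HERPUD1 (log2 fold change -0.65 ± 0.05 SE) and the stress sensor gene ERN1 (-0.60 ± 0.09 SE) fell, and the endoplasmic reticulum co-chaperone genes SDF2L1 (0.47 ± 0.09 SE) and DNAJB11 (0.36 ± 0.05 SE) rose. Heat-shock protein genes were higher: 14 of 16 rose and 2 did not pass, 14 also when adjusted over the list alone. The list median was 0.69 (camera adjusted p = 5.7e-17; adjusted p = 0.15 with an estimated correlation). HSPH1 rose from 76.1 ± 7.07 to 223 ± 9.13 CPM (SD, n = 3), and HSPA1B rose 2.18-fold, although reads of HSPA1B and its near-identical copy HSPA1A cannot be told apart with certainty. Cytosolic ribosomal protein genes fell by small amounts: 68 of 77 fell and 9 did not pass, with 69 lower and 2 higher when adjusted over the list alone. The median of these genes was -0.24 (camera adjusted p = 2e-12; adjusted p = 0.31 with an estimated correlation). With scaling by library totals alone 51 fell and 3 rose, and with the correction for GC content and length 57 fell and 4 rose. RPL13A (log2 fold change -0.46 ± 0.04 SE) and RPL3 (-0.45 ± 0.04 SE) fell the most.

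Genes of NAD+ metabolism and the sirtuins showed no shared shift by camera, while fry, which does not compare a list with other genes, called the first list higher (adjusted p = 0.016) and the second lower (adjusted p = 0.0055). Of 21 NAD+ biosynthesis and consumption genes 9 rose, 7 fell and 5 did not pass, with 9 higher and 8 lower when adjusted over the list alone. Their median was -0.05, their mean 0.16 and the camera direction upward, so these differed in sign (adjusted p = 0.75; adjusted p = 0.75 with an estimated correlation). KYNU, an enzyme of the kynurenine pathway towards NAD+, had 90 counts in shSIRT1 and 7 in shfirefly, a ratio of 13.04 (95% exact interval 6.07 to 33.4), and NUDT12, a hydrolase of NAD+ and NADH, rose (log2 fold change 0.62 ± 0.10 SE). The nicotinamide methyltransferase gene NNMT (-0.57 ± 0.05 SE), the nicotinamide riboside kinase gene NMRK1 (-0.48 ± 0.08 SE) and NAMPT, the rate-limiting salvage enzyme chosen after its values were seen (-0.36 ± 0.04 SE), fell. Of 7 sirtuin genes 3 fell and 4 did not pass, 3 also when adjusted over the list alone. As a list their median was -0.23 (camera adjusted p = 0.17; adjusted p = 0.41 with an estimated correlation). That median was -0.11 with the correction for GC content and length and -0.11 with library totals alone, with 2 lower and 1 higher under each. Besides SIRT1, the cytoplasmic deacetylase gene SIRT2 fell by 0.44 on the log2 scale. Without a filter on low counts the sirtuin list passed the test (adjusted p = 0.048). SIRT1, a named hairpin target, was the lowest member of this list, which was not tested without it. Of 25 transcription factors and cofactors that SIRT1 deacetylates 11 fell, 4 rose and 10 did not pass, with 15 lower and 4 higher when adjusted over the list alone. Members had a median of -0.19 (camera adjusted p = 0.036; adjusted p = 0.28 with an estimated correlation). That list test was lost without shSIRT1 replicate 3 (adjusted p = 0.062), with the correction for GC content and length (0.076) and with library totals alone (0.090). Library totals alone gave 9 lower and 7 higher. EPAS1 and the repressor gene BCL6 (log2 fold change -0.78 ± 0.06 SE) fell the most and E2F1 (0.68 ± 0.07 SE) rose the most. EPAS1 is the other named hairpin target, and this list was not tested without it. Of 30 histone deacetylases and chromatin regulators 14 rose, 6 fell and 10 did not pass, 14 and 6 also when adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.045; adjusted p = 0.22 with an estimated correlation). Its test was lost without shfirefly replicate 1 (0.052), without shfirefly replicate 2 (0.061), without shfirefly replicate 3 (0.057), without shSIRT1 replicate 2 (0.067), without both libraries numbered 3 (0.051), with the replicate block (0.055), with upper-quartile scaling (0.080) and with the stricter filter (0.072). The histone demethylase gene KDM1A rose from 149 ± 2.79 to 236 ± 5.25 CPM (SD, n = 3).

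Cartilage genes went both ways. Of 18 tested genes of cartilage matrix and chondrocyte identity 5 rose, 4 fell and 9 did not pass, 5 and 4 also when adjusted over the list alone. The median was -0.10, the mean -0.15 and the camera direction upward, so these differed in sign (adjusted p = 0.97; adjusted p = 0.97 with an estimated correlation). The collagen IX gene COL9A2 (log2 fold change 1.35 ± 0.32 SE) and the transcription factor gene FOXC1 (0.84 ± 0.11 SE) rose, and the cytokine-like gene CYTL1 fell (-1.19 ± 0.31 SE). SOX9, the master regulator of chondrocyte fate, rose from 43.7 ± 2.54 to 53.1 ± 1.17 CPM, while ACAN, the main cartilage proteoglycan core protein, fell from 1.51 ± 0.270 to 0.679 ± 0.194 CPM (SD, n = 3); both were chosen after their values were seen. Of 8 tested hypertrophic chondrocyte and osteoblast markers 4 fell, 1 rose and 3 did not pass, 4 and 1 also when adjusted over the list alone. The list median was -0.28 (camera adjusted p = 0.099; adjusted p = 0.24 with an estimated correlation; fry called the list lower, adjusted p = 0.00067). Osteonectin (SPARC) fell from 2268 ± 59.5 to 1398 ± 17.4 CPM (SD, n = 3).

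Of the 5 lists of markers of other cell types, camera with the preset correlation called 1, while fry, which does not compare a list with other genes, called each of them (adjusted p of 0.011 or lower). Of 10 tested embryonic kidney and neuronal markers of the HEK293 type, the cell type most used to package lentivirus, 6 rose, 1 fell and 3 did not pass, 6 and 1 also when adjusted over the list alone. The median of these genes was 0.33 (camera adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation). The test was lost without both libraries numbered 3 (adjusted p = 0.067). NEFM, a neurofilament gene, had 59 counts in shSIRT1 and 2 in shfirefly, a ratio of 29.9 (95% exact interval 7.92 to 252.8), the RNA-binding protein gene LIN28B rose 3.63-fold, and EYA1 fell (log2 fold change -0.69 ± 0.20 SE). Of 10 epithelial markers 3 rose, 1 fell and 6 did not pass, 3 and 1 also when adjusted over the list alone (camera adjusted p = 0.26; adjusted p = 0.57 with an estimated correlation), with CLDN4 and KRT7 higher and KRT17 lower. Of 9 endothelial markers 3 fell, among them TIE1 and ROBO4, and 6 did not pass, 3 also when adjusted over the list alone (camera adjusted p = 0.36; adjusted p = 0.51 with an estimated correlation). Of 5 tested leukocyte markers 3 fell, among them CD3D, and 2 did not pass, 3 also when adjusted over the list alone (camera adjusted p = 0.20; adjusted p = 0.31 with an estimated correlation). Of 10 skeletal and smooth muscle markers 3 rose, 3 fell and 4 did not pass, 3 and 3 also when adjusted over the list alone (camera adjusted p = 0.17; adjusted p = 0.30 with an estimated correlation), with MYOD1 (log2 fold change -2.20 ± 0.36 SE) and MYH8 (-1.20 ± 0.12 SE) lower.

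The authors' deposited table gave adjusted p-values for 18868 genes, of which 3895 rose and 3673 fell at the same threshold, with 360 and 659 of these changed by at least 2-fold. Of the genes called here, 3790 rose and 3621 fell in the authors' deposited table too, and 0 had opposite calls. Both sets of log2 fold changes come from the same 6 libraries, so close values were to be had and give no independent support. Their Pearson r was 0.99984 across genes, which are not independent replicates. For SIRT1 and EPAS1 the authors' deposited table lists log2 fold changes of -0.876 and -0.972.

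No list test passed at an adjusted p under 0.05 once the correlation between genes was estimated per list, although 2 lists were higher and 11 lower at an unadjusted p under 0.05 with camera, and fry called 13 higher and 27 lower. Fold changes also followed transcript GC content, with a median log2 fold change of 0.20 in the tenth of genes with the lowest GC content and -0.11 in the highest.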

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

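The alternatives named as chosen after seeing the data are library totals alone, the GC and length correction and the fit without both libraries numbered 3; the rest were planned. Of 181 named genes 180 were called, and 164 of these kept their call and direction under every alternative run. All but SIRT1, EPAS1, HIF1A and ARNT were named for being called or after their values were seen. These counts therefore do not describe the called genes as a whole. HIF1A, not called, reversed from 0.03 to -0.022 with upper-quartile factors (adjusted p = 0.67), to -0.17 with the GC and length correction (adjusted p = 0.00042), and to -0.0042 without shfirefly replicate 2; leaving out single libraries gave -0.0042 to 0.067, and its adjusted p ranged from 0.00042 to 0.97 over all alternatives. The cause was not tested. SIRT1 and EPAS1 kept call and direction under every alternative run. The count of genes at least 2-fold higher was 551 with library totals alone, a scaling that moved the median of all genes to 0.13, and 239 with the stricter filter, against 363; that of genes at least 2-fold lower was 437 with the stricter filter, which tests 13898 genes, against 707. Leaving out single libraries gave 3824 to 4425 genes higher, 3902 to 4444 lower, 354 to 513 at least 2-fold higher and 675 to 812 at least 2-fold lower. Without both libraries numbered 3, 4404 rose and 4079 fell; DESeq2 gave 4004 and 3889. Lists called numbered 7 higher and 22 lower. With an estimated correlation 0 were higher and 0 lower (2 and 11 at an unadjusted p under 0.05), and with fry 13 were higher and 27 lower. The camera runs differed only in the correlation setting. Estimates ran from -0.072 for leukocyte markers to 0.598 for cytosolic ribosomal proteins, against the preset 0.01. They were 0.489 for the hypoxia list outside glycolysis and 0.462 for the S-phase list. The preset p-values of such lists thus rest on a lower correlation than was estimated. Fry does not compare a list with other genes. With the replicate block 4711 genes rose and 4465 fell. Deviations of same-numbered libraries correlated at 0.095, 0.057 and 0.323, so the numbers were not taken to pair samples. Deviations within a group sum to 0, so these values depend on each other and cannot exclude a pairing. The library shSIRT1 replicate 3 correlated best with its own number, while replicates 1 and 2 correlated best with shfirefly replicates 2 (0.168) and 1 (0.105). Both libraries numbered 3 deviated from their group means in the same way with GC content (Spearman -0.218 in shfirefly and -0.200 in shSIRT1). The other libraries had 0.086 to 0.147. The cause of this shared pattern was not tested. The planned share of mitochondrial counts was not run, as those genes were not analysed here. At these depths a count of 0 in a library allows a level of up to 0.0968 to 0.115 CPM.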

Other observations

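The tests of technical explanations and of the hairpin's identity in this part were chosen after the results were seen; the test of MITF targets and the count of other splits were fixed before their results were seen. Clock genes were mostly lower in shSIRT1: of 18 circadian clock genes 12 fell, 2 rose and 4 did not pass, 12 and 2 also when adjusted over the list alone. Their median was -0.51 (camera adjusted p = 4.6e-06; adjusted p = 0.15 with an estimated correlation). The repressor gene NR1D1 fell from 59.2 ± 4.51 to 21.9 ± 0.589 CPM (SD, n = 3) and CLOCK rose (log2 fold change 0.64 ± 0.07 SE). Of 53 interferon-stimulated genes 26 fell, 7 rose and 20 did not pass, 26 and 7 also when adjusted over the list alone (median -0.23, camera adjusted p = 0.00019; adjusted p = 0.21 with an estimated correlation), led by IFITM1 (-1.50 ± 0.30 SE) and the antigen-presentation gene HLA-B, which fell from 274 ± 13.4 to 100 ± 2.28 CPM (SD, n = 3), while HERC6 and DDX60 rose. Library totals alone gave 21 lower and 9 higher in this list, with a median of -0.11. Of 25 FOXO targets 15 fell, 3 rose and 7 did not pass, 15 and 3 also when adjusted over the list alone (median -0.29, camera adjusted p = 0.00042; adjusted p = 0.16 with an estimated correlation), with PDK4, which restrains pyruvate dehydrogenase, at -1.66 ± 0.23 SE and BCL2L11 at 0.68 ± 0.12 SE; library totals alone gave 14 lower and 8 higher. Of 35 p53 targets 17 fell, 7 rose and 11 did not pass, 17 and 7 also when adjusted over the list alone (median -0.08, camera adjusted p = 0.014; adjusted p = 0.31 with an estimated correlation); library totals alone gave 13 lower and 11 higher with a median of 0.04, which is -0.09 relative to all genes. GDF15 fell 2.46-fold and CDKN1A, the cell cycle inhibitor p21 (chosen after its values were seen), 1.43-fold, while AEN rose. Of 44 autophagy and lysosome genes 23 fell, 2 rose and 19 did not pass, 23 and 2 also when adjusted over the list alone (median -0.25, camera adjusted p = 1.1e-06; adjusted p = 0.21 with an estimated correlation), with GABARAPL1 lower and MITF higher; library totals alone gave 20 lower and 9 higher. Of 12 tested replication-dependent histone genes 7 fell and 5 did not pass, 8 when adjusted over the list alone (median -0.61, camera adjusted p = 0.0012; adjusted p = 0.16 with an estimated correlation), among them H2BC5 and H1-2. Histone genes held 0.00679% of the counts in shSIRT1 and 0.0110% in shfirefly (exact two-sided permutation test, p = 0.1, the smallest possible). Most mRNAs of this class lack the poly(A) tail that mRNA library kits select for, so their counts also depend on library preparation, which was not tested.

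Signalling lists were mixed. Of 31 TGF-β and BMP response genes 17 fell, 6 rose and 8 did not pass, with 17 lower and 7 higher when adjusted over the list alone (median -0.20, camera adjusted p = 0.00077; adjusted p = 0.16 with an estimated correlation), with SMAD6 1.79-fold higher; library totals alone gave 15 lower and 10 higher. Of 23 YAP and TEAD targets 13 fell, 6 rose and 4 did not pass, 13 and 6 also when adjusted over the list alone (median -0.16, camera adjusted p = 0.0091; adjusted p = 0.31 with an estimated correlation), with GADD45A lower and AMOTL1 higher; library totals alone gave 9 lower and 8 higher, with a median of -0.04. Of 27 immediate-early genes 14 fell, 2 rose and 11 did not pass, 14 and 2 also when adjusted over the list alone (median -0.43, camera adjusted p = 0.0011; adjusted p = 0.21 with an estimated correlation), with ATF3 and DUSP1 lower and SPRY4 higher. That median was -0.22 with the GC and length correction (12 lower, 5 higher) and -0.30 with library totals alone (11 lower, 5 higher). Camera did not call the following lists, while fry called those of Wnt targets (adjusted p = 0.0013), fatty-acid genes (0.045), the respiratory chain (0.049) and the BCL2 family (0.036) higher. Of 19 Wnt targets 8 rose, 3 fell and 8 did not pass, 8 and 3 also when adjusted over the list alone (adjusted p = 0.27), with the stem-cell receptor gene LGR5 2.72-fold higher. Of 26 cholesterol synthesis and SREBP target genes 15 rose, 5 fell and 6 did not pass, with 15 higher and 6 lower when adjusted over the list alone (adjusted p = 0.28), INSIG1 being 1.90-fold lower. Of 32 fatty-acid genes 11 rose, 7 fell and 14 did not pass, 11 and 7 also when adjusted over the list alone (adjusted p = 0.50), with PPARGC1B 2.85-fold higher and SCD 1.61-fold lower. Of 74 nuclear-encoded respiratory chain genes 21 rose, 12 fell and 41 did not pass, with 21 higher and 11 lower when adjusted over the list alone (adjusted p = 0.34); 40 rose with library totals alone and 35 with the GC and length correction. Of 36 antioxidant and NRF2 targets 14 rose, 6 fell and 16 did not pass, with 15 higher and 7 lower when adjusted over the list alone (adjusted p = 0.54), with AKR1C1 1.84-fold higher and HMOX1 2.36-fold lower. With library totals alone 23 of them rose and 6 fell, and the median went from 0.07 to 0.19. Of 26 BCL2 family and caspase genes 11 rose, 5 fell and 10 did not pass, with 11 higher and 6 lower when adjusted over the list alone (median -0.06 and mean -0.02 but upward by camera, adjusted p = 0.60), with BCL2 higher and BMF lower.

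Fold changes fell with GC content (Spearman -0.212 across genes) and the abundant genes mostly fell, so both library GC bias and scaling were weighed as technical sources of the opposite shifts of hypoxia and S-phase genes. The tables argue against GC bias as the whole cause. Scaling moves all genes by about the same amount, so it could not by itself produce shifts in opposite directions. With the GC and length correction the median of the hypoxia list was -0.82 (median SE 0.0480) and that of the S-phase list 0.66 (median SE 0.0595). With library totals alone in place of TMM they were -0.68 (median SE 0.0417) and 0.79 (median SE 0.0619). Relative to the median of all genes these were -0.81 and 0.67, so the change of scaling was no test of the opposite shifts. The median SE is that of single genes and does not measure the spread of a list median. The shifts may then reflect a biological difference between the groups, as a hypothesis found and tested on the same data. A difference in cell density or growth stage of the cultures was left untested. All libraries of a group carried the same labelled hairpin. Effects of a hairpin on other genes, and differences between the transduced cultures, therefore cannot be told apart from effects of lower SIRT1 or EPAS1.

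The same explanations were weighed for the small, broad fall of ribosomal protein genes, which are short and abundant. Their median was -0.19 (median SE 0.0425) with the GC and length correction and, in place of -0.24 with TMM, -0.12 (median SE 0.0356) with library totals alone. The size of the fall thus depended on the scaling, and a smaller fall remained under each. Relative to the median of all genes it was -0.24 with library totals alone. The median SE is that of single genes, so it does not measure the spread of the list median. A biological difference remains a hypothesis, and differences in RNA quality or library preparation between the groups were not tested.

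Because the labels name 2 hairpin targets, the falls of SIRT1 and EPAS1 were set against each other. Had the hairpin been directed against EPAS1, EPAS1 might have fallen the more. The difference of log2 fold changes, EPAS1 minus SIRT1, was -0.095 with an SE of 0.0973, and with the GC and length correction the order turned, with -0.90 for EPAS1 and -0.98 for SIRT1. The named targets cannot be told apart from these levels: both genes fell by about the same factor, and either fall could follow from the other.

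RAB38 and GPR143, both melanosome genes and known targets of the transcription factor MITF, were among the largest rises while MITF rose 1.58-fold. A wider rise of MITF targets was a candidate explanation, and a list of 27 other melanocyte targets was written before their values were seen. Of the 16 tested, 4 rose, 6 fell and 6 did not pass, with a median of -0.16 (median SE 0.0999; camera p = 0.34 with the preset and 0.36 with an estimated correlation), while fry gave p = 0.00089 in the downward direction. Among them GPNMB fell by 1.15 on the log2 scale, and PIR (0.69) and MREG (0.36) rose. These values argue against a rise of the targets as a set and leave the rise of the pair unexplained.

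The 6 libraries form 10 splits of 3 against 3, and 1 of the 10, the real one, gave 8760 genes; the highest of the others gave 0 with edgeR, and up to 339 genes at an unadjusted p under 0.05. Every other split held libraries of both groups on each side. The difference between the groups then added to the spread within each side, so few calls could arise. No other tool was run on the splits. With 10 splits a share under 0.05 cannot be reached.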
